A study of Homo sapiens with 18 samples.

How the data were processed

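The study measured RNA from HEK293 cells, a human embryonic kidney line, that carry a doxycycline-inducible gene for HA-tagged MBNL1. MBNL1 is an RNA-binding protein that regulates alternative splicing, and it is bound up by expanded repeat RNA in myotonic dystrophy. Per the labels, cells were given 0, 100, 170, 250, 280 or 1000 ng/mL doxycycline, with 3 libraries per dose and 18 libraries in all. Per the labels, total RNA was treated with DNase on the column, depleted of ribosomal RNA and made into directional libraries. Per the submitters' processing notes, reads were aligned with STAR 2.7.9a to the hg38 build. The rMATS version, its annotation and any trimming are not given in the sources used here.

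The authors deposited 5 rMATS files of skipped exons, each comparing 0 ng/mL with 1 induced dose. Per the file headers, each event holds the counts of reads over its splice junctions and within the exon, for the form with the exon and the form without it. The same deposited tables give the effective lengths of both forms, the inclusion level of each library and the difference of inclusion levels as 0 ng/mL minus the induced dose. The deposited p-values and their false discovery rates come from the authors' rMATS test of each event. All differences printed here run the other way, as dose minus 0 ng/mL. The dose of each column was taken from the names of the tables. The 0 ng/mL counts were identical in all 5 tables, with 0 events that differed. Each cell lists 3 libraries without a replicate number, so libraries are named by dose and by place in that list (the first, the second or the third listed library). Whether the replicates were separate cultures is not given in the sources used here, so the p-values measure the spread between these libraries, which may be technical in part.

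The tables held between 75272 and 81333 events. Joining them on exon and flanking exon coordinates left 55986 events in 45553 exons of 11391 genes. PSI (percent spliced in, the share of transcripts that include an exon, from 0 to 1) was recomputed from the counts divided by the effective lengths, and it matched the deposited inclusion level to within 5e-04. For each exon the event with the most reads was kept. An exon was tested if it had a mean of at least 20 reads per library in every dose and at least 20 reads of each form over all libraries. These filters left 19279 exons. GENCODE release 29 named the region of each exon, and 97.9% of the tested exons matched an annotated exon exactly. Of the tested exons, 12237 lay in coding sequence, 2988 in coding sequence and UTR, 1983 in UTR, 1666 in non-coding transcripts, and 405 were not annotated. Coordinates are those of the deposited tables in hg38, counted from 1.

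The libraries held between 9224184 reads in joined events (the first listed library at 100 ng/mL) and 25522697 (the second listed library at 170 ng/mL). The median number of reads per tested exon ranged from 70 to 241 between libraries. The SD of PSI between libraries of a dose had a median of 0.0224 and a 90th percentile of 0.0949. Comparing libraries of a dose exon by exon gave a mean chi-square between 1.92 and 3.36, so no library was a copy of another of its dose.

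The main test was a quasi-binomial model of inclusion against skipping counts for each exon, fitted to all 18 libraries with 12 residual degrees of freedom. The dispersion was moderated across exons with limma (squeezeVar, with a trend over depth) and held at 1 or above. Its median after moderation was 2.19, the prior had 35.4 degrees of freedom, and 0% of the exons lay at the lower bound. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the exons tested. An exon is called changed at an adjusted p below 0.05 with a difference of mean PSI of at least 0.1. Errors of differences are standard errors from the libraries of the compared doses.

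The comparisons were each dose against 0 ng/mL, each dose against the next lower one, 1000 against 100 ng/mL, and any difference among the 6 doses. The half-response dose of an exon is the lowest dose, by linear interpolation, from which the change stays at 0.5 or more of the change at 1000 ng/mL. It was computed for exons called at 1000 ng/mL with an absolute change of at least 0.2, with 100 bootstrap draws for its interval and 100000 resamples for the comparison of gained with lost exons. Gene lists were compared with 10000 random lists matched on tested exons per gene and read depth. The MBNL motif YGCY and the control motif RGCR (Y is C or T, R is A or G) were counted within exons in GENCODE transcript sequences and compared by permutation with 100000 resamples.

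A level for each gene was read from its event with the most reads among those with a mean PSI of at least 0.95 at every dose, with at least 10 reads per library on average. The log2 of RPM (reads scaled to the library total over these events, 0.5 added to the count and 1 to the total) was tested with limma in 7265 genes. This level is read from junction and exon reads of 1 exon and not from whole transcripts. Gene lists at this level were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry.

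The comparisons, thresholds, gene lists and the rule for naming exons were fixed before the data were examined. The rule names, among called exons whose 3 libraries at one dose all lie beyond the 3 at the other, the 12 largest rises and 12 largest falls at 1000 ng/mL, the 4 largest each way at each other dose, and the 3 largest each way at each neighbouring step, with 1 exon per gene. It adds the 6 lowest and 6 highest half-response doses among exons that changed by at least 0.3, the 4 called exons with the largest change in each list, and each called exon of MBNL1, MBNL2, MBNL3 and INSR. Some exons that the rule names are not reported here.

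The alternatives were limma on the log2 inclusion to skipping ratio, the same with the place in the list as a block, no lower bound on the dispersion, no trend of the dispersion, other read minimums (10 or 50), a PSI threshold of 0.2 or none, every event kept, only the 6 libraries compared, all events of a table, PSI without length normalisation, and the deposited false discovery rate. For the other results they were interpolation over the logarithm of dose plus 10, other PSI limits, the largest change as the full response, the sum over all MBNL1 events, median ratio scaling, other matching of lists and motif controls, and leaving out each library in turn.

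The steps were tested on simulated data. Exon counts were drawn with the dispersion that the model had estimated and with no structure shared between libraries. The shares of false calls hold for such data and may differ in the real libraries. With changes planted in the comparison of 1000 against 0 ng/mL over 19279 exons, the model recovered 8.8% of PSI changes of 0.1, 32% of 0.2, 62.4% of 0.3 and 89.2% of 0.4, and 5.13% of its calls were false. The limma test of log ratios recovered 0.8%, 5.2%, 31.2% and 53.6% of the same changes, and 1.30% of its calls were false. In the simulated comparison of 100 against 0 ng/mL, where nothing was planted, 6.78% of the exons had an unadjusted p below 0.05 and 1 was called. For the comparison of 1000 against 0 ng/mL, the gene level test recovered 73% of log2 changes of 1 and 100% of log2 changes of 2 in 7265 genes, with 5.98% of its calls false. A half-response dose planted at 200 ng/mL in 489 exons came back as a median of 204.4 ng/mL. Software versions were R 4.3.3, limma 3.58.1, data.table (version 1.17.8), Python 3.11.15 and matplotlib 3.10.9.

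Other kinds of splicing events, whole-gene expression and protein levels were not analysed here, and no library given doxycycline without the transgene was analysed here. Motifs in introns were not counted, because no genome sequence was used.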

Results

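The data are exon inclusion measurements in HEK293 cells at 6 doses of doxycycline (0, 100, 170, 250, 280 and 1000 ng/mL), which switches on an HA-tagged MBNL1 gene. The study asks how splicing outcomes vary as the amount of 1 splicing factor is raised. Inclusion is given as PSI, the share of transcripts that include an exon, from 0 to 1. PSI values are means of 3 libraries ± SD (n = 3), and changes are differences of mean PSI, dose minus 0 ng/mL unless another pair is named. The 18 libraries held between 9224184 and 25522697 reads in the joined splicing events, and 19279 exons were tested.

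MBNL1 reads rose with the doxycycline dose. MBNL1 is the gene that the transgene carries, and its reads come from the transgene and from the cell's own gene together. At an MBNL1 exon present in nearly all its transcripts (chromosome 3, 152432717 to 152432920, a coding exon of 204 bases with a mean of 3640 reads per library), the level was 204 ± 53.0 RPM (reads scaled to the library total over the events used for gene levels) at 0 ng/mL and 255 ± 116 at 100 ng/mL. It was 500 ± 111 RPM at 170, 931 ± 115 at 250, 1127 ± 155 at 280 and 1984 ± 65.6 at 1000 ng/mL. In the limma test of log2 RPM the MBNL1 level was higher at 250 ng/mL by 2.21 (adjusted p 0.00174), at 280 ng/mL by 2.49 (adjusted p 0.000303) and at 1000 ng/mL by 3.31 (adjusted p 3.15e-06), each with an SE of 0.28. These log2 changes correspond to folds of 4.64, 5.62 and 9.95. The changes at 100 ng/mL (0.22, adjusted p 1) and 170 ng/mL (1.30, adjusted p 0.942) did not pass the test, which adjusts over all genes measured. The change at 170 ng/mL had an SE of 0.28 and corresponds to a fold of 2.46. All 3 libraries at 170 ng/mL (378.5 to 596 RPM) lay above the 3 at 0 ng/mL (165.1 to 264.1 RPM). Those at 100 ng/mL (123.8 to 342.5 RPM) overlapped with them. The change at 100 ng/mL ran from -0.0544 without the second listed library at that dose to 0.6794 without the first, and did not pass whichever library was left out. Leaving out the first listed library at 100 ng/mL, which has the fewest MBNL1 reads of its dose, let the change at 170 ng/mL pass (adjusted p 0.00358).

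**Figure D1:**
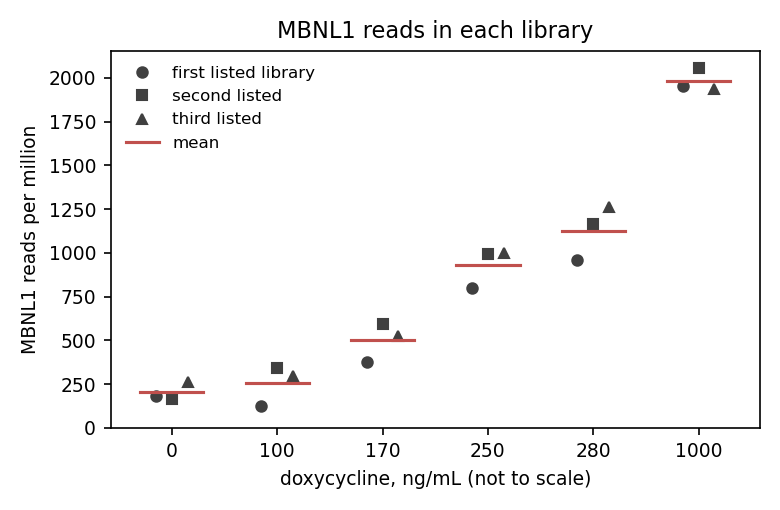
MBNL1 reads in RPM (vertical axis) in each library against the doxycycline dose in ng/mL (horizontal axis, doses not to scale), with 1 marker per library by its place in the list and a short line at each mean. The mean rises from 204 at 0 ng/mL to 1984 at 1000 ng/mL, and the first listed library lies lowest at 100, 170, 250 and 280 ng/mL.

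The comparison of 100 with 0 ng/mL asks whether the lowest induction moved any exon, and no exon passed. Among the lowest p-values were exons of ABCD4, a lysosomal transporter of vitamin B12, GLA, a lysosomal galactosidase, and MBNL1 itself. The ABCD4 exon (chromosome 14, 74290027 to 74290118, coding) differed by -0.301 (SE 0.0749), and the MBNL1 exon of 54 bases differed by -0.138 (SE 0.0348), both with an adjusted p of 0.728. The quasi-binomial model called 0 exons with 1028 at an unadjusted p below 0.05, where exact p-values would give 964 by chance. In simulated data without a change in this comparison, 6.78% of the exons had such a p under this model. The 1028 are therefore no sign of an excess. The limma test of log ratios called 0 as well, while the authors' deposited false discovery rate passed 163 of the tested exons, among them the MBNL1 exon (0.000113).

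At 170 ng/mL the largest rises of inclusion were in CLASP1, which tracks growing microtubule ends, in ARFGAP2, which acts on the coat of Golgi vesicles, in TEAD1, the DNA-binding partner of YAP, and in NUMA1, which organises the mitotic spindle. The largest falls were in FAM122B, in ENAH, which promotes actin filament growth, in APH1A, a subunit of gamma-secretase, and in MBNL1. The CLASP1 exon (chromosome 2, 121445449 to 121445496, coding, 48 bases) went from 0.0846 ± 0.0348 to 0.485 ± 0.0296, a change of 0.4 (SE 0.0264, adjusted p 4.75e-05). The ARFGAP2 exon rose by 0.37 (SE 0.0832, adjusted p 0.00109) and the NUMA1 exon by 0.305 (SE 0.0335, adjusted p 1.85e-06). The TEAD1 exon of 12 bases (chromosome 11, 12878889 to 12878900, coding) went from 0.202 to 0.515 (adjusted p 0.0359). The FAM122B exon changed by -0.379 (adjusted p 4.42e-05), the ENAH exon by -0.349 (adjusted p 0.000584), the APH1A exon by -0.237 (adjusted p 5.91e-05) and the MBNL1 exon of 54 bases by -0.168 (adjusted p 1.07e-05). In all, 37 exons in 32 genes were called at 170 ng/mL, 24 with higher and 13 with lower inclusion, and their median absolute change was 0.190. The count was 23 without the second listed library at 0 ng/mL, and 22 and 24 without the second and the third at 170 ng/mL. Under limma on log ratios ARFGAP2 (adjusted p 0.0768), TEAD1 (0.647), NUMA1 (0.204), ENAH (0.146) and MBNL1 (0.261) were not called. Without the second listed library at 170 ng/mL ARFGAP2 lost its call (adjusted p 0.0521), and TEAD1 lost its call without any 1 of the 6 libraries compared (0.0683 to 0.309).

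At 250 and 280 ng/mL the early exons went further and others joined them. PALM, a membrane-bound protein of cell processes, THOC5, an mRNA export factor, and TUFT1 gained exons, and MFSD13A, PRELID3A and SCARF2 lost them. At 250 ng/mL ARFGAP2 rose by 0.636 (adjusted p 1.22e-07), CLASP1 by 0.6 (1.74e-08), PALM by 0.589 (1.17e-06) and TUFT1 (chromosome 1, 151562091 to 151562165, coding) by 0.566 (0.0014). FAM122B changed by -0.613 (2.14e-10), MFSD13A by -0.577 (1.11e-05), ENAH by -0.541 (2.03e-10) and SCARF2 by -0.514 (0.0359) at that dose. At 280 ng/mL the largest rises were in PALM (0.705, adjusted p 2.59e-08), CLASP1 (0.671, 1.2e-09), ARFGAP2 (0.668, 2.14e-08) and THOC5 (0.638, 5.21e-13). The largest falls at 280 ng/mL were in FAM122B (-0.63, adjusted p 1.51e-10), MFSD13A (-0.596, 8.61e-06), PRELID3A (-0.579, 7.81e-05) and ENAH (-0.577, 1.55e-11). At 250 ng/mL 232 exons in 193 genes were called, 94 higher and 138 lower, and at 280 ng/mL 358 exons in 284 genes, 155 higher and 203 lower. SCARF2 kept its call at 250 ng/mL without the first listed library at that dose and lost it without any other 1 of the 6 compared (adjusted p 0.0966 to 0.142). It also lost the call under limma with the place in the list as a block (adjusted p 0.0507). The limma test of log ratios called 143 exons at 250 ng/mL and 209 at 280 ng/mL.

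**Figure D2:**
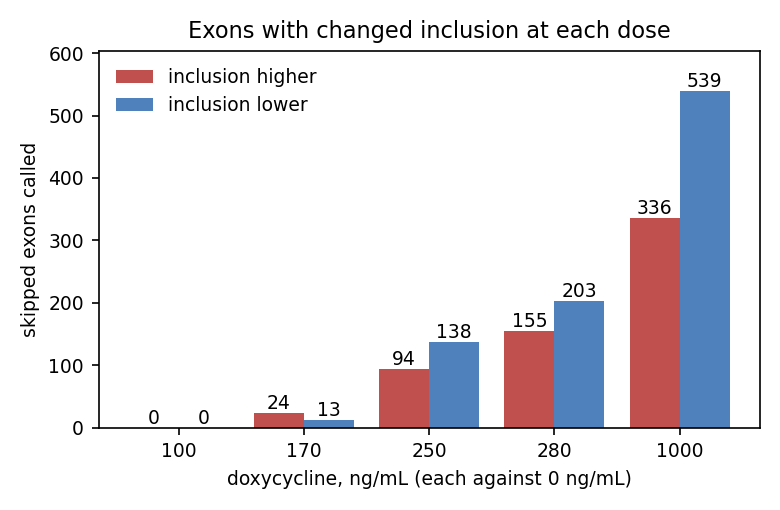
Number of exons called with higher and with lower inclusion (vertical axis) at each doxycycline dose against 0 ng/mL (horizontal axis, ng/mL, doses not to scale). The total goes from 0 at 100 ng/mL through 37, 232 and 358 to 875 at 1000 ng/mL.

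At 1000 ng/mL the largest rises were mostly in short coding exons with low inclusion without doxycycline. They lie in genes of vesicle traffic (ARFGAP2, ARAP1, VPS39), of the cytoskeleton (CLASP1, MACF1, NUMA1) and of signalling (LEF1, MAP2K7). The ARFGAP2 exon (chromosome 11, 47172710 to 47172751, 42 bases) went from 0.0542 ± 0.0194 to 0.893 ± 0.0244, a change of 0.839 (SE 0.018, adjusted p 9.81e-11). LEF1, a transcription factor of the Wnt pathway, gained an exon of 84 bases (chromosome 4, 108081586 to 108081669), from 0.0357 ± 0.0325 to 0.851 ± 0.03 (adjusted p 6.53e-12). CLASP1 reached 0.876 ± 0.0208, a change of 0.792 (adjusted p 2.51e-12). THOC5 gained an exon of 33 bases (chromosome 22, 29531078 to 29531110), from 0.0843 to 0.87 (adjusted p 4.89e-16), and PALM one of 132 bases (chromosome 19, 740352 to 740483), from 0.247 ± 0.042 to 0.991 ± 0.0163 (adjusted p 4.5e-09). ARAP1 (chromosome 11, 72692753 to 72692785) went from 0.14 to 0.875 and VPS39 (chromosome 15, 42192066 to 42192098), which tethers membranes at the lysosome, from 0.0141 to 0.65, each with an exon of 33 bases. MACF1 (chromosome 1, 39480920 to 39481030) changed by 0.687, NUMA1 (chromosome 11, 72012401 to 72012442) by 0.648, MAP2K7 (chromosome 19, 7905808 to 7905855) by 0.632 and CCDC88C (chromosome 14, 91285395 to 91285836) by 0.597. The adjusted p of these 4 lay between 4.89e-16 and 2.09e-05.

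The largest falls at 1000 ng/mL were mostly in exons that nearly every transcript included without doxycycline. They lie in the COPII coat gene SEC31A, the actin regulator ENAH, the secretase subunit APH1A, the kinase MAPK12 and ARHGAP17, among others. The FAM122B exon (chromosome X, 134772143 to 134772283, in a non-coding transcript) went from 0.95 ± 0.0244 to 0.164 ± 0.115, a change of -0.785 (SE 0.0676, adjusted p 4.96e-15). PRELID3A (chromosome 18, 12429350 to 12429436) went from 1 to 0.289 ± 0.0427 (adjusted p 3.44e-07), and MFSD13A (chromosome 10, 102470665 to 102471117) from 0.971 ± 0.0511 to 0.261 ± 0.137 (adjusted p 3.79e-08). TSPAN4 (chromosome 11, 862550 to 862741) changed by -0.689 and RHBDD3 (chromosome 22, 29261200 to 29261425) by -0.68. SEC31A (chromosome 4, 82842140 to 82842481) went from 0.893 to 0.243 (adjusted p 2.05e-10), and ENAH (chromosome 1, 225517196 to 225517990, 795 bases) from 0.764 ± 0.0663 to 0.115 ± 0.0538 (adjusted p 3.53e-15). APH1A (chromosome 1, 150267957 to 150267991, 35 bases) fell to 0.363 ± 0.116 (adjusted p 6.34e-13), SCARF2 (chromosome 22, 20429225 to 20429340) to 0.361 ± 0.275 (0.000877) and MAPK12 (chromosome 22, 50249103 to 50249454, in a non-coding transcript) to 0.355 ± 0.137 (1.05e-06). TPRA1 (chromosome 3, 127575185 to 127575265) changed by -0.591 and ARHGAP17 (chromosome 16, 24939364 to 24939597) by -0.581. In all, 875 exons in 694 genes (9.31% of the genes tested) were called, 336 with higher and 539 with lower inclusion, and their median absolute change was 0.219. The limma test of log ratios also called each of the exons named above for this dose.

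**Figure D3:**
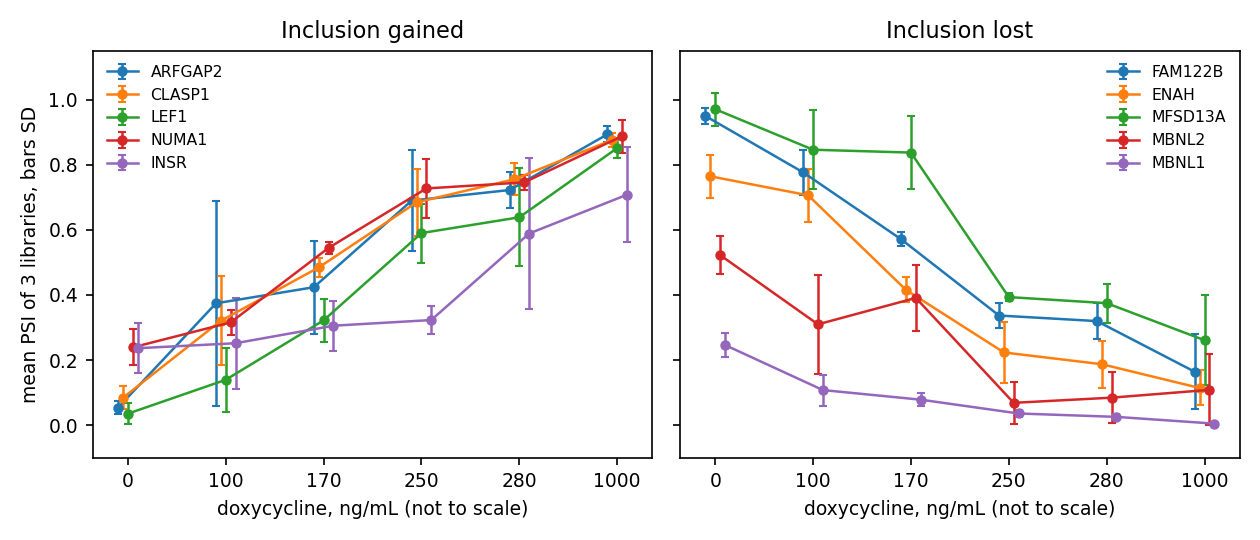
PSI (vertical axis) against doxycycline dose in ng/mL (horizontal axis, doses not to scale) for exons that gained inclusion (left: ARFGAP2, CLASP1, LEF1, NUMA1, INSR) and lost it (right: FAM122B, ENAH, MFSD13A, MBNL2, MBNL1), with points at the mean of 3 libraries and bars of 1 SD. ARFGAP2 goes from 0.0542 to 0.893 and FAM122B from 0.95 to 0.164.

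The exons of MBNL1, MBNL2 and INSR are classic readouts of MBNL activity. The MBNL1 and MBNL2 exons of 54 bases help to hold those proteins in the nucleus, and the INSR exon makes the longer form of the insulin receptor, which is reduced in myotonic dystrophy muscle. The MBNL1 exon (chromosome 3, 152446704 to 152446757) went from 0.246 ± 0.0369 through 0.108 ± 0.0477 at 100 ng/mL and 0.0786 ± 0.0198 at 170 ng/mL to 0.00504 ± 0.00129 at 1000 ng/mL (change -0.241, SE 0.0213, adjusted p 4.24e-17), and its reads include those of the transgene. The MBNL2 exon (chromosome 13, 97356796 to 97356849) went from 0.523 ± 0.0592 to 0.0689 ± 0.0648 at 250 ng/mL (adjusted p 0.00117) and stood at 0.109 ± 0.109 at 1000 ng/mL (change -0.414, SE 0.0715, adjusted p 0.00152). Under limma on log ratios the MBNL2 exon was not called at 250 (adjusted p 0.0585) or 280 ng/mL (0.051). The INSR exon of 36 bases (chromosome 19, 7150497 to 7150532) stayed between 0.237 ± 0.077 and 0.323 ± 0.043 up to 250 ng/mL and reached 0.708 ± 0.146 at 1000 ng/mL (change 0.471, SE 0.0951, adjusted p 0.00106). Its change of 0.352 at 280 ng/mL did not pass (adjusted p 0.067), and it passed without the first listed library at 280 ng/mL (0.00532), with only the 6 compared libraries fitted (0.0198) and by the authors' deposited false discovery rate (0.0229). No MBNL3 exon was among those tested.

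Genes already reported as MBNL targets carried changed exons more often than other genes. Of 63 reported targets tested, 30 had a called exon at 1000 ng/mL where matched random lists gave 9.07 (adjusted p 6e-04). The list gave 38 called exons, 20 higher and 18 lower, and 44 when adjusted over the list alone. Its largest changes were in CLASP1, NUMA1, VPS39 and TEAD1 (0.202 to 0.793, adjusted p 2.69e-06). Cytoskeleton and motor genes, led by CLASP1, MACF1, ENAH and NUMA1, had a called exon in 28 of 83 against 11.8 (adjusted p 6e-04), with 38 called exons and 44 adjusted over the list alone. Membrane traffic genes, led by ARFGAP2, SEC31A and VPS39, had one in 25 of 78 against 10.6 (adjusted p 6e-04), with 32 called exons and 35 adjusted over the list alone. For SEC31A a second form of the exon (chromosome 4, 82842185 to 82842481) changed by -0.64. Kinase and signalling genes, with MAP2K7, ARHGAP17 and INSR, had one in 21 of 84 against 11.5 (adjusted p 0.00675), with 23 called exons and 25 adjusted over the list alone. A second ARHGAP17 exon (chromosome 16, 24929613 to 24929660) rose by 0.462 while the first fell. Both tested MBNL family genes, MBNL1 and MBNL2, were called against 0.251 (adjusted p 0.0191), with 2 called exons and 2 adjusted over the list alone. The reads of the MBNL1 exon include those of the transgene, which alone could bring about its call. Only the MBNL2 call is free of this, so the list result says little. The lists share members, so these are not independent results.

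Adhesion and junction genes also passed, though 1 library could decide it, and 3 other lists did not pass. AFDN, which anchors nectins to actin, gained an exon of 21 bases (chromosome 6, 167913403 to 167913423), from 0.4 to 0.981 (adjusted p 1.73e-11). TJP1, the scaffold of tight junctions, gained one of 240 bases (chromosome 15, 29719777 to 29720016), from 0.098 to 0.554 (4.2e-10), and the polarity gene SCRIB (chromosome 8, 143791876 to 143791913) and the amyloid precursor gene APP (chromosome 21, 25905024 to 25905077) changed by -0.397 and -0.342. Of 44 adhesion genes 11 had a called exon against 5.56 (adjusted p 0.0453), with 12 called exons and 16 adjusted over the list alone. That call was lost without the first (adjusted p 0.0869) or the third (0.0567) listed library at 1000 ng/mL. Among splicing factors 9 of 96 genes had a called exon against 10.4 (adjusted p 0.775), with 12 called exons and 14 adjusted over the list alone. They include RBFOX2 (chromosome 22, 35746473 to 35746561), which changed by -0.365 (adjusted p 9.94e-09), and a UTR exon of CELF1 (chromosome 11, 47500861 to 47500932), which rose by 0.283 (0.00151). Transcription and chromatin genes had one in 17 of 86 against 11.7 (adjusted p 0.164), with 27 called exons and 27 adjusted over the list alone, and the list passed without the third listed library at 0 ng/mL (0.0458). NFIX (chromosome 19, 13078613 to 13078735) changed by -0.516 and PRDM2 (chromosome 1, 13773078 to 13773188) by 0.438, and PRDM2 lost its call without the first listed library at 1000 ng/mL (adjusted p 0.205). Ion channel and calcium genes had one in 5 of 29 against 3.06 (adjusted p 0.393), with 8 called exons and 12 adjusted over the list alone, and the list passed without the first listed library at 0 ng/mL (0.0237). CAMKK2 (chromosome 12, 121244573 to 121244615) went from 0.00257 to 0.568 (adjusted p 1.44e-11), and SLC4A7 (chromosome 3, 27431298 to 27431669) rose by 0.299 (0.00214). ITPR3 (chromosome 6, 33671165 to 33671306) changed by -0.197 (0.00297) and lost its call without the second listed library at 1000 ng/mL (0.177) and under limma (0.179). CAMK2G (chromosome 10, 73853192 to 73853246) changed by 0.185 (0.0191) and lost its call without the second listed library at 0 ng/mL (0.0848) or the first at 1000 ng/mL (0.135).

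The exons called at intermediate doses were nearly all called again at the top dose. CLASP1, NUMA1, ARFGAP2, FAM122B and ENAH were called at 170, 250, 280 and 1000 ng/mL in the same direction. Of the exons called at 170 ng/mL 36 of 37 were called at 1000 ng/mL in the same direction, of those at 250 ng/mL 222 of 232, and of those at 280 ng/mL 315 of 358, with 0 in the opposite direction. Independent lists would share 0.782, 5.50 and 8.38. The comparisons share the 0 ng/mL libraries, which cannot be split into separate controls, so part of the excess may come from them. In 20 simulated data sets without any change, a mean of 0.6, 0.3 and 0.4 exons were called at these 3 doses, too few to measure sharing (means of 0.05, 0 and 0 shared calls). In the same data sets 87.5% of the exons with an unadjusted p below 0.05 at 170 ng/mL had the same sign at 1000 ng/mL, so the shared direction alone says little.

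Between neighbouring doses few exons moved far enough to be called. From 100 to 170 ng/mL inclusion rose in NUMA1 (0.316 to 0.544, adjusted p 0.00548), in the myosin light chain gene MYL6 (chromosome 12, 56160626 to 56160670, 0.241 to 0.405, 9.93e-10) and in an exon of 9 bases of PSAP (chromosome 10, 71823888 to 71823896), which makes lysosomal saposins (0.381 to 0.504, 0.00523). Inclusion changed by -0.231 in APH1A (adjusted p 0.0049) and by -0.175 in an ENAH exon form of 111 bases (chromosome 1, 225517196 to 225517306, 0.000722). That step had 6 called exons in 5 genes, 3 each way. None of these calls held under limma on log ratios (adjusted p 0.576 to 0.956). Without the second listed library at 170 ng/mL NUMA1 (0.0941), PSAP (0.0645), APH1A (0.0812) and ENAH (0.0554) lost their calls. Without the second listed library at 100 ng/mL NUMA1 (0.156), PSAP (0.161) and APH1A (0.0604) did, and without the third APH1A did (0.0882). The count of 6 was 3 and 2 without the second listed library at 100 and at 170 ng/mL. From 250 to 280 ng/mL 0 exons were called by the quasi-binomial model and 0 by limma. At an unadjusted p below 0.05 the quasi-binomial model had 762 there, where exact p-values would give 964 by chance.

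From 170 to 250 ng/mL inclusion rose in PALM (0.34, adjusted p 0.0478), THOC5 (0.296, 0.00319) and AFDN (0.247, 0.0387). Inclusion changed by -0.444 in MFSD13A (adjusted p 0.0246), by -0.234 in FAM122B (0.0459) and by -0.262 in DMPK (chromosome 19, 45770971 to 45771056, 0.0387), the kinase gene whose repeat expansion causes myotonic dystrophy. In all 23 exons in 20 genes were called, 9 higher and 14 lower. THOC5 lost its call without the second listed library at 250 ng/mL (0.0835). PALM (0.146 to 0.277), DMPK (0.082 to 0.484) and FAM122B (0.0556 to 0.439) lost theirs without any 1 of the 6 libraries, and AFDN (0.082 to 0.413) and MFSD13A (0.0659 to 0.198) without any but the third listed library at 170 ng/mL. The count of 23 was 8, 8 and 11 without the first, the second and the third listed library at 170 ng/mL, and 5 and 7 without the second and the third at 250 ng/mL. Limma on log ratios called 0 exons at this step, with adjusted p from 0.719 to 0.986 for these genes.

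From 280 to 1000 ng/mL most called exons lost inclusion. SH2B2, an adaptor of insulin signalling (chromosome 7, 102300522 to 102301279), changed by -0.486 (adjusted p 0.0414), MAPK12 by -0.401 (0.0314) and the cadherin gene CDH24 (chromosome 14, 23049027 to 23049275) by -0.332 (0.0257). USP33 (chromosome 1, 77745421 to 77745599) rose by 0.196 (0.045), the mitochondrial fission gene MFF (chromosome 2, 227329606 to 227329783) by 0.184 (0.0294) and LPCAT1 (chromosome 5, 1521347 to 1521480) by 0.176 (0.00783). In all 48 exons in 45 genes were called, 7 higher and 41 lower (85.4%). LPCAT1 lost its call without the first listed library at 280 ng/mL (0.139) or at 1000 ng/mL (0.0679). USP33 (0.0859 to 0.296) lost it without the first or second listed library of either dose, MFF (0.0562 to 0.35) and SH2B2 (0.0782 to 0.306) without any but the second at 1000 ng/mL. MAPK12 (0.0514 to 0.294) lost it without any but the first at 1000 ng/mL, and CDH24 (0.0809 to 0.21) without any but the third at 1000 ng/mL. The count of 48 was 7 and 28 without the first and the third listed library at 280 ng/mL, and 76 without the first at 100 ng/mL. Limma on log ratios called 0 exons at this step (adjusted p 0.0696 to 0.719 for these genes).

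Compared with 100 ng/mL, the largest changes at the top dose were in LEF1, PALM, ARAP1, TSPAN4, PRELID3A and SEC31A. LEF1 rose by 0.712 (adjusted p 9.06e-11), PALM by 0.687 and ARAP1 by 0.683, and TSPAN4 changed by -0.68, PRELID3A by -0.674 and SEC31A by -0.666. In all 706 exons in 560 genes were called, 256 higher and 450 lower. The test for any difference among the 6 doses called 702 exons in 551 genes, of which 251 had higher and 451 lower inclusion at their largest change.

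The half-response dose is given by name for exons that changed by at least 0.3. An exon of INF2, a formin that severs and builds actin filaments, was among the lowest of these (chromosome 14, 104715284 to 104715340), with a half-response dose of 115.1 ng/mL and a bootstrap interval of 75.8 to 155.0. Lower values among these exons were those of ZNF708 (66.2, interval 33.5 to 251.7), ZC3H11A (84.0, 59.0 to 382.8), GKAP1 (86.6, 33.2 to 311.6), PRELID2 (90.4, 68.8 to 730.1) and FGFR3 (93.3, 66.9 to 263.1). At the other end of this set stood the cadherin CDH24 (635.0, interval 579.5 to 675.7) and SNX7 (659.2, 499.0 to 738.4). CDAN1 stood at 624.1 (466.5 to 867.2). EMSY (609.8, interval 294.8 to 736.5), ERVK13-1 (633.5, 136.2 to 806.8) and NRF1 (663.1, 294.4 to 819.8) did not respond steadily. The share of the full change fell from 0.61 at 170 ng/mL to 0.0775 at 280 ng/mL in EMSY and from 0.826 to 0.0177 in ERVK13-1. In NRF1 it fell from 0.636 at 250 ng/mL to -0.0686 at 280 ng/mL. Their high values rest on the rule that the change stays at 0.5 or more. ZC3H11A moved to 134.5 and 177.2 without the first listed library at 100 and at 170 ng/mL, and GKAP1 to 52.4 and 136.0 without the first and second at 100 ng/mL. PRELID2 moved to 285.5 and 320.7 without the second and the third listed library at 0 ng/mL, to 181.5 without the third at 170 ng/mL and to 284.8 without the first at 280 ng/mL. With interpolation over the logarithm of dose ZNF708 moved to 38.9, CDAN1 to 516.5, CDH24 to 526.5 and SNX7 to 549.5. The value of CDH24 then lay below its bootstrap interval, which does not cover the choice of scale. INF2 moved to 89.9 without the second listed library at 100 ng/mL.

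Over the 489 exons with a half-response dose, which changed by at least 0.2, the median was 253.9 ng/mL, with quartiles of 208.7 and 335.0. Exons that gained inclusion responded at a median of 232.6 ng/mL (181 exons) and those that lost it at 259.1 ng/mL (308 exons), a difference of -26.5 ng/mL (permutation p 3e-05, across exons, which are not independent replicates). The difference was -64.0, -9.28 and -28.7 ng/mL when computed from the first, the second and the third listed libraries alone. Of these exons 9 (1.84%) responded below 100 ng/mL, 38 between 100 and 170, 182 (37.2%) between 170 and 250, 109 between 250 and 280, and 151 (30.9%) above 280 ng/mL. The median exon had covered 5.55 ± 4.87% of its full change at 100 ng/mL, 23.4 ± 7.01% at 170, 52.3 ± 8.26% at 250 and 62.6 ± 9.46% at 280 ng/mL.

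**Figure D4:**
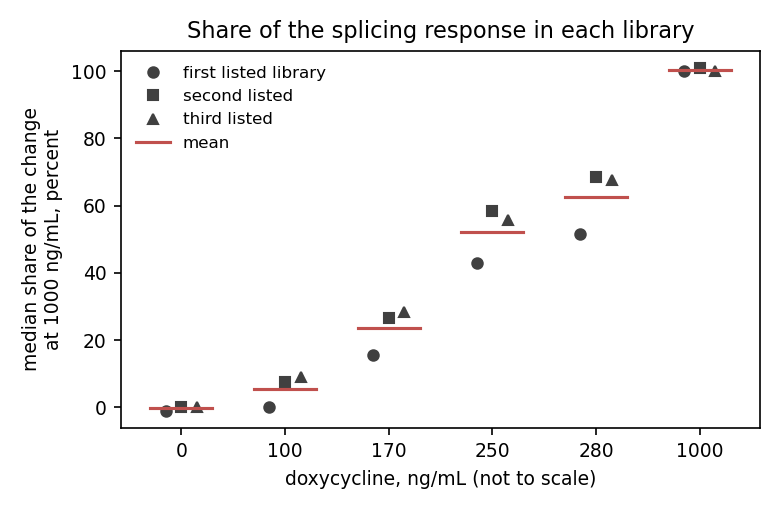
Median share of the full PSI change in percent (vertical axis) in each library against the doxycycline dose in ng/mL (horizontal axis, doses not to scale), with 1 marker per library by its place in the list and a short line at each mean. The means run from 5.55 at 100 ng/mL to 62.6 at 280 ng/mL, and the first listed library lies lowest at each dose from 100 to 280 ng/mL.

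The comparison of motifs asks whether the changed exons carry YGCY, the sequence MBNL proteins bind. Exons that lost inclusion at 1000 ng/mL held 3.44 YGCY per 100 positions (SE 0.0965, 536 exons) against 1.54 in 13913 unchanged exons, a difference of 1.90 (permutation adjusted p 2e-05, the smallest these permutations can give). Exons that gained inclusion held fewer, 1.18 per 100 positions (326 exons, difference -0.36, adjusted p 2.67e-05). The control motif RGCR was also denser in lost exons by 0.483 (adjusted p 2e-05) and did not differ in gained exons (-0.0781, adjusted p 0.317). Lost exons were richer in G and C, with a median of 61.4% against 50%. Against unchanged exons matched on G and C content and length, the YGCY excess in lost exons was 1.24 (adjusted p 2e-04, the smallest these permutations can give) and the RGCR difference was -0.0964 (adjusted p 0.221). Overlapping forms of an exon count as separate exons here. The SE and the permutations treat their shared sequence as independent, so both may understate the error.

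**Figure D5:**
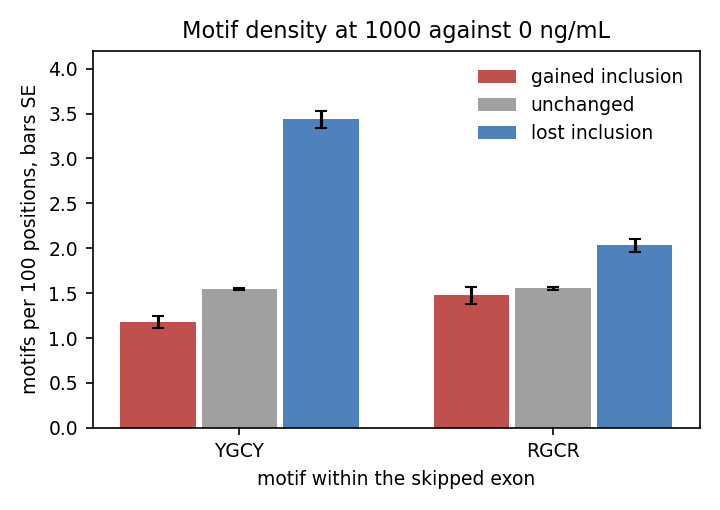
Mean number of YGCY and RGCR motifs per 100 positions within the exon (vertical axis) for exons that gained inclusion, lost inclusion or were unchanged at 1000 ng/mL (horizontal axis), with bars starting at 0 and error bars of 1 SE. YGCY stands at 3.44 in lost exons against 1.54 in unchanged and 1.18 in gained exons.

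Nearly every exon called here was also called by the authors' deposited test with the same PSI threshold. The numbers were 37 of 37 at 170 ng/mL, 231 of 232 at 250, 357 of 358 at 280 and 862 of 875 at 1000 ng/mL, in the same direction in each case. The deposited test called more of the tested exons, namely 163, 304, 636, 827 and 1468 at the 5 doses in rising order.

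At the level of gene reads, stress and mitochondrial genes were examined because an overexpressed protein can strain the cell. Doxycycline and MBNL1 rose together, and no library given doxycycline without the transgene was analysed. Changes in these genes can therefore not be assigned to either. SESN2, a target of the integrated stress response, rose at 1000 ng/mL by 0.93 on the log2 scale (SE 0.18, adjusted p 0.0226), and LONP1, a mitochondrial protease, changed by -0.81 (SE 0.15, adjusted p 0.0177). Of 16 stress response genes measured 1 was called, and 3 when adjusted over the list alone, with a median log2 change of 0.10 (camera adjusted p 0.0407). Of 11 mitochondrial unfolded protein response genes 1 was called, and 3 when adjusted over the list alone, with a median of -0.25 (camera adjusted p 0.0407). With an estimated correlation neither list passed (estimated-correlation adjusted p 0.316 for both), and fry gave an adjusted p of 0.0777 and 0.045. The 12 reference genes had a median of -0.13 (camera adjusted p 0.132), with 0 called and 0 adjusted over the list alone. Of the neuronal markers 2 were measured (camera adjusted p 0.229), and SYP changed by -1.05 (adjusted p 0.0361), with 1 called and 1 adjusted over the list alone, while no muscle marker was measured. SESN2 lost its call without the first (adjusted p 0.0836) or the third (0.0576) listed library at 0 ng/mL or the first (0.0537) or second (0.0713) at 1000 ng/mL, and LONP1 without the first (0.0843) or second (0.0884) at 0 ng/mL. SYP lost its call without 10 of the 18 libraries. Of 7265 genes 60 were called at 1000 ng/mL, 26 higher and 34 lower, and the count ran from 7 without the first listed library at 0 ng/mL to 273 without the first at 100 ng/mL.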

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

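The alternatives chosen only after the data were seen are the removal of the dispersion trend, median ratio scaling, the estimated correlation, motif controls matched on G and C content and length, the alternatives for single half-response exons, and leaving out libraries for gene lists, motifs and gene levels.

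The direction of each called result held under every alternative that could change it, except for the control motif RGCR in lost exons. That motif went from 0.483 to -0.0964 against the matched controls. For single exons, limma and the fit of only the 6 libraries compared reuse the same PSI differences, so they cannot change a direction. YGCY in lost and gained exons, MBNL1 reads at 250, 280 and 1000 ng/mL and the lists of reported targets, cytoskeleton, membrane traffic and kinase genes also kept their side of the threshold. Dropping the dispersion trend, changing the read minimums, keeping every event, fitting only the 6 libraries compared, using all events of a table and using PSI without length normalisation left each exon count within 1.5 times. No exon lay at the lower bound of the dispersion, so dropping that bound tests nothing.

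Limma on log ratios called fewer exons, 13, 143 and 209 at 170, 250 and 280 ng/mL, 0, 0 and 0 at the steps from 100 to 170, 170 to 250 and 280 to 1000 ng/mL, and 375 for any dose. With the place in the list as a block the counts were 13, 135, 221, 0, 0, 0 and 359. In simulated data this test recovered fewer planted changes at each size, with a smaller share of false calls (1.30% against 5.13%). Those data were drawn with the dispersion of the quasi-binomial model, so neither share measures the false calls in the real libraries. A PSI threshold of 0.2 gave 17, 122, 185 and 489 exons at 170 to 1000 ng/mL, 2, 7 and 16 at the 3 steps, 399 for 1000 against 100 ng/mL and 430 for any dose. These fall by construction. Without a PSI threshold 60 exons were called at 170 ng/mL and 76 from 280 to 1000 ng/mL. The deposited false discovery rate passed 163, 304, 636, 827 and 1468 of the tested exons at the 5 doses, and the cause was not tested. At a threshold of 0.2 the deposited test called 100% of the exons called here at 250 and at 280 ng/mL.

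The median half-response dose of gained exons was 251.4 with changes of at least 0.1 and 214.0 with at least 0.3, and the cause was not tested. At a PSI threshold of 0.2 the transcription and chromatin list passed (1.86 times the random mean, adjusted p 0.0465) and the adhesion list did not (2.13, 0.0913), nor did adhesion with lists matched on exon number alone (1.97, 0.0525). The mean log2 changes of the stress response and mitochondrial lists did not pass with median ratio scaling (0.18 and -0.24, adjusted p 0.0583 for both) or with an estimated correlation (0.19 and -0.24, adjusted p 0.316 for both). The causes were not tested.

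Leaving out 1 library at a time gave 22 to 50 exons at 170 ng/mL, lowest without the second listed library at 170 ng/mL, with 24 without the third there and 23 without the second at 0 ng/mL. The step from 100 to 170 ng/mL ran from 2 to 9 (2 without the second listed library at 170 ng/mL, 3 without the second at 100), that from 170 to 250 from 5 to 33 (8, 8 and 11 without the 3 libraries at 170, 5 and 7 without the second and the third at 250), and that from 280 to 1000 from 7 to 76 (7 and 28 without the first and the third at 280, 76 without the first at 100). The counts at 250, 280 and 1000 ng/mL ran from 163 to 264, 247 to 396 and 702 to 951, and 0 exons were called at 100 ng/mL in each case. The median half-response dose of gained exons ran from 210.5 (without the third listed library at 0 ng/mL) to 241.7. The log2 change of MBNL1 reads at 100 ng/mL ran from -0.0544 (without the second listed library at 100 ng/mL) to 0.6794 (without the first) and passed in no case. That at 170 ng/mL ran from 1.16 to 1.503 and passed without the first listed library at 100 ng/mL (adjusted p 0.00358).

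Over left-out libraries the ratio of the ion channel list ran from 1.68 to 2.71 (2.71 without the first listed library at 0 ng/mL, adjusted p 0.0237), that of transcription and chromatin genes from 1.34 to 1.66 (1.66 without the third at 0 ng/mL, 0.0458), and that of adhesion genes from 1.90 to 2.32 (lost without the first and the third at 1000 ng/mL, 0.0869 and 0.0567). The stress response list ran from 0.0715 to 0.286 and did not pass without the third listed library at 0 ng/mL (adjusted p 0.267) or the second (0.304) or the third (0.0757) at 1000 ng/mL. The mitochondrial list ran from -0.281 to -0.168 and did not pass without the second at 0 ng/mL (0.103) or the first (0.0554), the second (0.0739) or the third (0.0574) at 1000 ng/mL.

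Of 101 named exons and comparisons 30 changed their call under some alternative and 0 changed direction. Limma on log ratios ended 25 calls among the 101, and in 606 refits without 1 library of the compared doses 79 calls ended and 1 was added. No paired analysis was possible because the deposited columns carry no replicate number, so the place in the list stands in for it without being known to match. Motif windows of 100, 200 and 400 bases in introns were not run for want of a genome sequence. Small changes were often missed, as 8.8% of simulated PSI changes of 0.1 and 89.2% of those of 0.4 were recovered at 1000 against 0 ng/mL. A planted change of 0.1 lies at the PSI threshold of a call, so the threshold alone causes part of the misses at that size. The part that depth has in the misses was not tested.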

Other observations

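The test on MBNL2, the tests within doses and those of a swap and of low induction were chosen only after the results they concern were seen, while those on exon length, on the transgene, on YGCY and half-response dose, on the overlap of exons and on other splits were planned.

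The exons called at 1000 against 0 ng/mL doxycycline more often had a length divisible by 3 than other exons did. Such a length keeps the reading frame where the whole exon is coding. Coding exons here and in the result on very short exons include those in coding sequence and UTR, where length alone does not set the frame. A length divisible by 3 was found in 395 of 715 called coding exons (55.2%) and in 6246 of 14510 uncalled ones (43.1%), an odds ratio of 1.63 (Fisher's exact test p 2e-10, adjusted 4e-10). The share was 64.3% among exons that gained inclusion (151 of 235), such as ARFGAP2, LEF1 and THOC5, and 50.8% among those that lost it (244 of 480). Whether these groups differ from each other was not tested. The uncalled exons were not limited to alternatively spliced ones, so whether such exons in general have these lengths was not tested either.

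Very short exons were called at 1000 against 0 ng/mL doxycycline more often than others. Of 209 coding exons of 27 bases or fewer 33 were called (15.8%), against 682 of 15016 longer ones (4.54%), an odds ratio of 3.94 (Fisher's exact test p 8.2e-10). Of these short exons 23 gained and 10 lost inclusion, among them the exons of TEAD1 (12 bases) and AFDN (21 bases). Exons are not independent replicates, and the result may depend in part on which short exons had reads enough to be tested. Whether lost exons with more YGCY respond at lower doses stays open, since the Spearman correlation of YGCY density with the half-response dose was 0.0845 and within chance (permutation p 0.14, adjusted 0.276, across 305 exons).

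The MBNL1 exon of 54 bases loses inclusion as the dose rises, which might arise only because the transgene adds reads without the exon. Reads that skip it did rise, from 16 to 140 RPM, here scaled to the reads in tested exons. Reads that include it fell too, from 8.04 to 1.09 RPM, a ratio of 0.136 with the 3 libraries at 1000 ng/mL below the 3 at 0 ng/mL. That argues against transgene reads as the whole cause, since they cannot lower the inclusion reads. Whether the level of the cell's own MBNL1 RNA also fell, which would lower them too, was not tested. Its reads cannot be told from those of the transgene. The matching MBNL2 exon, which no transgene carries, fell from 2.93 to 0.562 RPM of inclusion reads, a ratio of 0.192, as splicing of both by the induced protein would give. These MBNL2 values rest on few reads, 9 to 32 per library at 0 ng/mL and 0 to 9 at 1000 ng/mL. How much transgene reads add to the MBNL1 fall stays open.

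Within a dose, libraries with more MBNL1 reads may show more of the splicing response. Over the 12 libraries at 100 to 280 ng/mL, each taken relative to the mean of its dose, MBNL1 reads and the share of the full response had a Pearson r of 0.668 (exact within-dose permutation p 0.0124, adjusted 0.0185 over 3 relations) and a Spearman correlation of 0.427 (exact p 0.108, adjusted 0.162), and r was 0.646 without the 2 libraries farthest from the median. Depth had an r of 0.115 (exact p 0.667), which decides nothing for or against it. The first listed library was lowest in both measures at 4 of 4 doses, and between the second and the third the one with more MBNL1 reads had the larger share at 0 of 4 doses (exact one-sided p 0.0625), so the relation rests on the first listed libraries. Something shared by those libraries, such as a batch or an earlier harvest, is as open as a lower MBNL1 level; r met the expectation written for it, and reading it as open was decided after these values were seen.

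At 100 ng/mL no exon was called, yet the split that puts the first and the second listed libraries at 0 ng/mL with the first at 100 ng/mL called 63 exons (35 higher, 28 lower), in HNRNPH1, EEF1D, RBM3 and SNRNP70 among others. Such a split points to a structure of the samples. A swap of the third listed library at 0 ng/mL with the first at 100 ng/mL is argued against, since over the exons called at 1000 against 170 ng/mL the former lay with its own dose (distance ratio 0.00179), although the first at 100 ng/mL lay nearer the 0 ng/mL libraries (2.93). The 63 exons shared 4 with the 520 called at 1000 against 170 ng/mL, where chance gives 1.70 (odds ratio 2.46, Fisher's exact test p 0.0901). Of the 63 exons 14 were also called at 1000 against 0 ng/mL, in the same direction, as low induction of the first library at 100 ng/mL would give. The 0 ng/mL libraries that both comparisons share could raise this count and this likeness of direction too. The first library at 100 ng/mL had 124 RPM of MBNL1, below the lowest library at 0 ng/mL (165 RPM). It also had the fewest reads of the 18 libraries, with a median of 70 per tested exon. The part that its depth has in these calls was not tested. Low induction in that library would give changes below those at 1000 against 0 ng/mL. Yet 54 of the 63 exons changed more than that and 10 had the opposite sign. At this dose the median responding exon had covered 5.55% of its change (mean of the 3 libraries). These values cannot decide on low induction, since exons called for their change tend to have inflated ones. Only 9 exons lay beyond the change at 1000 ng/mL by more than 2 SE. Low induction, read depth and another difference between libraries apart from the MBNL1 response all stay open.

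Other splits of the same libraries were counted for each exon comparison. For the test of any dose 702 exons were called against at most 229 in the other splits drawn. Only the real split, 1 of the 100, was as large, which is the smallest share these splits can give. Chance is thus unlikely to account for the count there. With 6 libraries there are 10 splits, too few for a share below 0.05. The real split called 0 exons at 100 ng/mL (63 in the highest other), 37 at 170 (2), 232 at 250 (0), 358 at 280 (0) and 875 at 1000 ng/mL (8). For the steps it called 6 from 100 to 170 ng/mL (1), 23 from 170 to 250 (0), 0 from 250 to 280 (0) and 48 from 280 to 1000 ng/mL (12), and 706 for 1000 against 100 ng/mL (22).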
